A study of Homo sapiens with 3 samples.

How the data were processed

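The series measured messenger RNA in HCT116 cells, a human colorectal cancer line. Cells received an shRNA knockdown system and were harvested at 36 or 48 h; the labels do not say which library had which time. There were 3 libraries: 1 control shRNA library (sh_control) and 2 libraries with shRNA against circRAPGEF5, a circular RNA named after its host gene RAPGEF5. The labels do not say whether the 2 knockdown libraries are separate hairpins, separate cultures or repeats of 1 culture. Per the labels' protocols, total RNA was isolated with TRIzol and a mirVana kit, and libraries were made with the TruSeq Stranded mRNA LT kit, which selects polyadenylated RNA.

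The deposited values are FPKM (fragments per kilobase of gene, scaled to the reads of each library), computed by the authors for 15625 genes with symbol, Entrez number and pathway names per gene. Per the submitters' processing notes, Trimmomatic, HISAT2 and the GRCh38.p13 genome were used. Their versions, the counting program, its strand setting and the gene annotation are not given in the sources used here. The names of KEGG pathways per gene are annotation text (other values) that the authors deposited with the table. Listed values of the 3 libraries formed ratios of whole numbers in 100% of genes, within a relative tolerance of 1e-09, once 1 depth factor per library was removed. The smallest whole reads that give these ratios summed to 14632390 in the control, 14832142 in knockdown library 1 and 15758794 in knockdown library 2. A common factor per gene cannot be seen from ratios, so true read numbers may be larger. On simulated values of 3956 genes, reads were recovered up to such a factor in 100% of genes. Depth was 1.01 and 1.07 times the control in the knockdown libraries. The list of genes encoded by the mitochondrial genome was not analysed here.

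Genes were tested on the log2(FPKM + 1) scale if their mean FPKM over the 3 libraries was at least 1, which left 11216 genes. On this scale the fold change of weakly expressed genes is understated. The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, the knockdown libraries against the control, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 control and 2 knockdown libraries there is 1 residual degree of freedom, and limma added 10.92 prior degrees of freedom. The lone control was assumed to vary like the knockdown libraries. Nothing in the labels gives separate cultures, so p-values measure only the spread between these libraries, which may be technical. An exact permutation of 1 library against 2 has 3 splits and cannot go below p = 0.33.

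The limma step was tested on simulated data for this comparison, with 11216 genes, 200 of them changed, in 20 runs. It called 4.6% of changed genes at 2-fold, 68.1% at 4-fold and 98.2% at 8-fold. Of all its calls, 15.5% were false at a nominal 5% (0.05). The excess came from the prior: the estimated prior degrees of freedom lay above the simulated 10.92 in 19 of 20 runs, with a median of 21.09. With the simulated prior in place of the estimate, 4.7% of calls were false. Adjusted p-values from this design are therefore too small on average. Members of a list were also adjusted over that list alone, from the same p-values and with no correction across lists.

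Genes changed at least 2-fold in the same direction in both knockdown libraries were counted as a description with no test. Because both fold changes share the control library, 1000 sets of unchanged libraries were simulated for the same counts and the same correlation. Of 25 gene lists fixed with the design, 21 had at least 5 tested members. These were compared with the other genes by limma's camera, with a preset inter-gene correlation of 0.01 and, beside it, an estimated one. With an estimated correlation camera uses only the 1 residual degree of freedom, so few lists or pathways could pass. A call lost in that setting therefore decides little. Simulated lists of 15 genes raised by 0.7 were called in 100% of runs, by an unadjusted p under 0.05 with the preset correlation. Their genes were drawn independently, so this does not cover lists whose genes vary together. KEGG pathways with at least 10 tested genes were tested in the same way. A list's median was also placed among 10000 random lists of the same size, matched on mean expression. The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 10 genes with the largest and the 10 with the smallest fold change by the knockdown library nearer to the control, among genes at least 2-fold in both. It adds 16 genes of the RAS-ERK pathway named in advance, and up to 4 members of each list described. Some genes that the rule takes are not reported here.

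Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, limma without the trend or with robust fitting, other fold thresholds, an estimated correlation, and leaving out each knockdown library. Added after the data were seen were limma's voom on the recovered reads, a prior set to 5 degrees of freedom, and fits with each knockdown library in the control's place. A comparison with the median of all genes was dropped because that median depends on how the libraries are scaled. It was -0.048 as deposited and -0.009 with median-ratio rescaling. A test of whether ATF4 targets fell as a whole was dropped because it held 2 of the genes it was meant to explain. Gene positions and lengths are from GENCODE release 29 on GRCh38, matched by Entrez number for 99.2% of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No circular RNA was matched in this gene table, so circRAPGEF5 itself was not analysed here.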

Results

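RNA-seq libraries of HCT116 colorectal cancer cells were compared between a control shRNA (1 library) and shRNA against circRAPGEF5 (2 libraries). The series title places the question in RAS/RAF/MEK/ERK signaling, a growth factor pathway. Depth, as the smallest whole reads behind the FPKM values, was 14632390 in the control and 14832142 and 15758794 in the knockdown libraries. Values below are FPKM, and fold changes are log2 differences of FPKM + 1 from the control. The control has no replicate, so it has no SD.

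The host gene RAPGEF5 (Entrez 9771, GRCh38 chromosome 7, 22118238 to 22357144), a guanine nucleotide exchange factor for RAP GTPases, was listed at 1.98 FPKM in the control. It was at 1.33 in knockdown library 1 and 2.73 in knockdown library 2, a mean log2 fold change of -0.01 ± 0.47 (SE) with a limma adjusted p of 0.998. The libraries lay on opposite sides of the control, and the sign of the mean turned under median-ratio rescaling (0.02) and quantile normalization (0.26). This is a gene-level value of the linear transcript and does not measure the circular RNA, so it does not check the knockdown.

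CPA4, a secreted carboxypeptidase (Entrez 51200, chromosome 7, 130293134 to 130324180), rose from 3.19 FPKM to 104 ± 16.2 (SD, n = 2), a log2 fold change of 4.64 ± 0.40 (SE) with a limma adjusted p of 0.000819. The genes that follow did not pass the test. NT5E, the surface enzyme that makes adenosine, was at 2.22 FPKM in the control and 26.5 and 18.4 in the knockdown libraries. ITGA2, a collagen-binding integrin subunit, was at 5.45 against 44.4 and 28.7, and PHLDA2 at 41.3 against 179 and 223. The MAPK phosphatase DUSP4 had a log2 fold change of 2.18, and the feedback inhibitor SPRY4 was at 5.09 against 39.5 and 24.4. The ribosome biogenesis factor MAK16 (log2 fold change 2.31), the RNA polymerase III transcription factor GTF3A (2.09) and the transporter SLC16A6 (2.15) were also among the higher genes of the naming rule.

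On the lower side, BMF, a pro-apoptotic gene, was at 6.79 FPKM in the control and 0.610 and 0.288 in the knockdown libraries. PHGDH, which starts serine synthesis, was at 32.2 against 5.03 and 8.95, and PCK2, a mitochondrial gluconeogenic enzyme, at 27.3 against 3.42 and 7.08. The neutral amino acid transporter SLC1A4 had a log2 fold change of -1.87, the glucocorticoid-induced gene TSC22D3 -1.96, COL4A3 -1.80, IGSF9 -2.10 and YPEL1 -2.13. TMSB15A (-2.89) has a near-identical copy, and the row named CD99-2 (-2.63) lies in the region shared by the X and Y chromosomes, so both are uncertain. None of these 10 genes passed limma's threshold, with adjusted p from 0.173 to 0.413.

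Of 11216 genes tested, limma called 2 higher, among them CPA4, and 0 lower, and 793 had an unadjusted p under 0.05 where chance gives 561. Both calls ended, leaving 0 calls, when limma's prior was set to 5 degrees of freedom, with no filter on low values, and with quantile normalization. Simulated data showed that limma's own estimate of that prior runs high in this design. The excess of unadjusted p-values over chance also ended with the prior set to 5. A smaller excess appeared with either knockdown library in the control's place, where limma estimated larger priors, which by themselves ease calls. A shift shared by the knockdown libraries would also recur there in part. These excesses therefore do not decide whether the excess is particular to the control. At least 2-fold in both knockdown libraries were 327 genes, 136 higher and 191 lower. The majority turned to higher genes with a pseudocount of 5 (62 higher, 39 lower) and with a mean FPKM of at least 5 (131 higher, 107 lower).

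**Figure D1:**
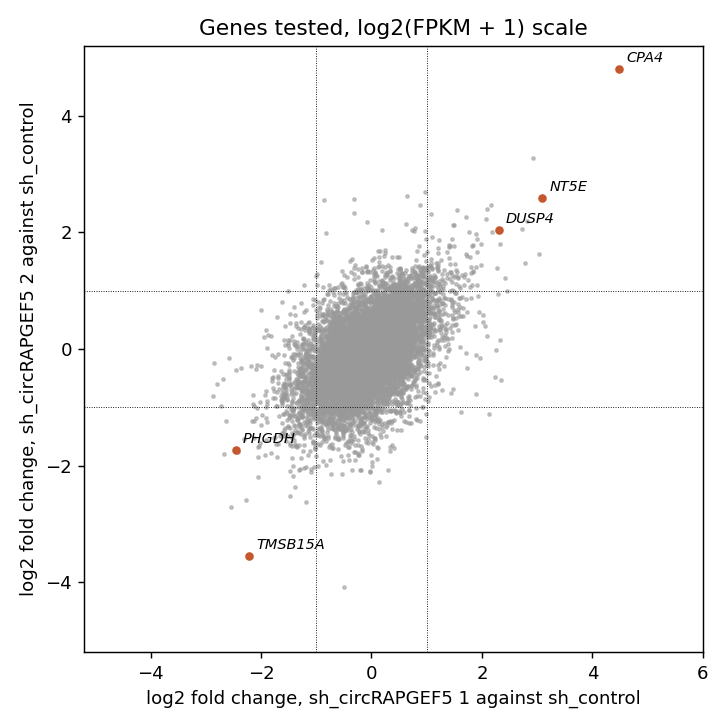
Log2 fold change of each of the 11216 tested genes in knockdown library 1 (horizontal axis) and knockdown library 2 (vertical axis) against the shared control, on the log2(FPKM + 1) scale; dotted lines mark 2-fold, and 5 labelled genes of the naming rule are in orange. CPA4 lies farthest out on the higher side, at 4.49 and 4.80.

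Target genes of MEK-ERK signaling were higher in both knockdown libraries. Of 15 tested members, 12 were higher in both, 1 was lower in both, and the list's median log2 fold change was 0.69 (0.77 and 0.52 in libraries 1 and 2). The median lay at percentile 99.99 among random lists matched on expression. With camera the adjusted p was 7.67e-08. The call was lost at an adjusted p = 0.714 with an estimated correlation. That setting leaves camera only 1 residual degree of freedom, so the loss decides little for this or any list below. Replication-dependent histones, a list fixed as a possible sign of RNA quality, had medians of 1.19 and 0.47 in the same libraries, with 5 of 9 tested members higher in both. Adjustment over a list alone, here and below, has no correction across lists and uses limma p-values that run small. Such passes are therefore lenient, and they were not repeated with a prior of 5 degrees of freedom. Adjusted over the MEK-ERK list alone, 6 members passed, against 0 over all genes tested. These were SPRY4, FOSL1 (an AP-1 subunit, 19.0 FPKM against 163 and 61.2), DUSP4, DUSP5 (38.2 against 140.0 and 97.2), DUSP6 (17.3 against 67.7 and 38.4) and EPHA2, which is outside the naming rule and was chosen after its values were seen. Other members differed between the libraries. CCND1, cyclin D1, was at 114 FPKM in the control and at 287 and 117, and ETV5 had log2 fold changes of 0.27 and -0.13. SPRY2 (0.42) and ETV4 (0.43) did not pass.

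**Figure D2:**
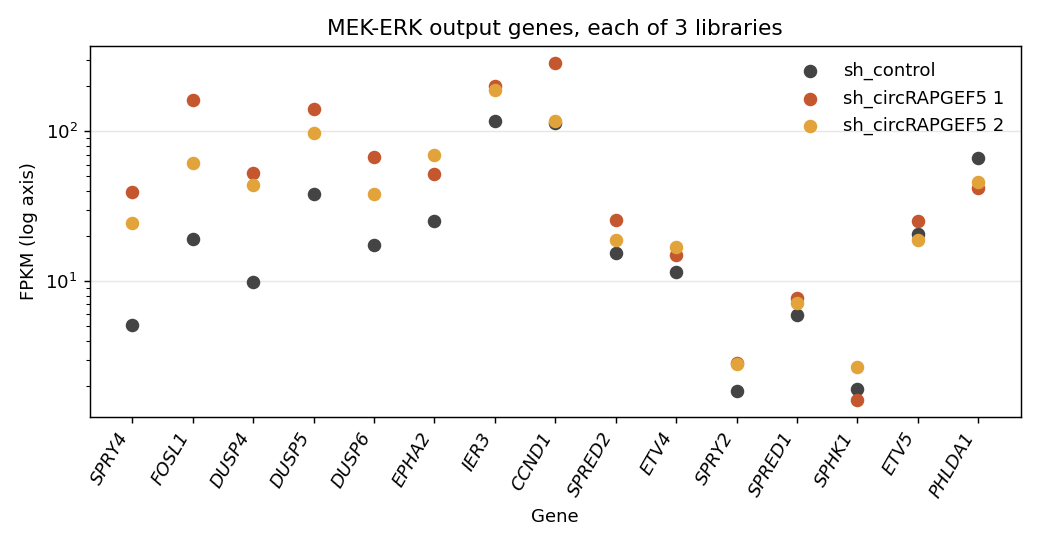
FPKM (log axis) of the 15 tested MEK-ERK output genes in each of the 3 libraries, 1 point per library, ordered by mean log2 fold change. In 12 of the 15 genes both knockdown libraries lie above the control.

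No shift of the genes that encode the pathway itself passed the test. Of 28 RAS-RAF-MEK-ERK components, 9 were higher and 12 lower in both libraries, with a median log2 fold change of -0.004, 0.038 under median-ratio rescaling, and a camera adjusted p of 0.64. None of the 28 passed adjusted over the list alone, as over all genes. The KEGG pathways MAPK signaling (198 genes, median -0.012, camera adjusted p 0.81) and Ras signaling (141 genes, -0.033, 0.961) did not pass either. BRAF had a log2 fold change of 0.57. MAP2K1 lay on opposite sides of the control, at -0.16 in library 1 and 0.78 in library 2, and MAPK3 was at -0.84 and -0.17. NRAS (1.18), HRAS (0.75), ERBB3 (-0.96) and SOS2 (-0.72) were the members farthest from 0. Immediate-early genes had a median of 0.35 and a camera adjusted p of 0.075 (0.806 with an estimated correlation). Library 1 carried that median, at 0.50 against 0.08 in library 2, which lay at percentile 62.91 among random lists. Their list became a call with no filter on low values (adjusted p 0.00508). In it MYC (1.18) and ATF3 (0.93) were higher, FOS (-0.51 and -1.93) and KLF2 (-1.78) lower, and EGR1 was at 1.22 and 0.00 in the 2 libraries. KLF2 alone passed adjusted over the list alone, and none passed over all genes. RAP GTPase cycle genes had a median of -0.03 (0.116 with quantile normalization, camera adjusted p 0.584), with RAPGEF1 at -1.54, RAP2A at -1.03, RAP1GAP2 at 0.60 and SIPA1 at -0.57.

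In the list of G2 and mitosis genes, 19 of 21 were lower in both libraries, with a median log2 fold change of -0.49 (-0.68 in library 1, -0.27 in library 2, camera adjusted p 4.25e-06). The call was lost with an estimated correlation, at an adjusted p = 0.714. The 116 genes of the KEGG cell cycle pathway did not pass (median -0.143, camera adjusted p 0.782). MKI67, the proliferation marker, was at 93.5 FPKM against 21.6 and 45.6, and BIRC5, survivin, at 77.3 against 32.5 and 26.2. These genes, CENPF (-1.41) and NUSAP1 (-1.27) passed adjusted over the list alone and did not pass over all genes. DNA replication and S phase genes had a median of -0.40 (-0.51 and -0.20 in libraries 1 and 2, camera adjusted p 0.0325), 14 of 23 lower in both. The call ended with no filter on low values (adjusted p = 0.0735) and with an estimated correlation (adjusted p = 0.714). Its members farthest from 0 were E2F1 at -1.18, CDT1 at -0.77, POLA1 at -0.75 and CDC45 at -0.73. MYC targets and ribosome biogenesis genes had a median of 0.59 (0.52 and 0.71, camera adjusted p 7.87e-06, and adjusted p = 0.714 with an estimated correlation), 15 of 20 higher in both, led by RRP12, SRM, NOP16 and RRP9, the last at 0.96. Cytosolic ribosomal proteins had a median of -0.37 (-0.20 and -0.50, camera adjusted p 0.00188), 24 of 26 lower in both. This call ended with no filter on low values (adjusted p = 0.0826) and with an estimated correlation (adjusted p = 0.714). Among random lists matched on expression the median lay at percentile 37.44. The KEGG ribosome pathway, a wider set of 127 genes, had a median of -0.205 and a camera adjusted p of 0.961. RPL3 (-1.10), RPL10A (-1.03) and RPS2 (-0.84) led the ribosomal protein list, whose genes have many pseudogene copies and are uncertain. Replication-dependent histones, whose main transcripts lack poly(A) tails, had a median of 0.61 (camera adjusted p 0.00783, and adjusted p = 0.714 with an estimated correlation). Gene-level values do not show whether the reads came from transcripts with or without tails, so the list may not measure RNA quality. Of 9 tested, 5 were higher in both libraries, 1 was lower in both and 3 lay on opposite sides, and 0 passed adjusted over the list alone. The members farthest from 0 were H2AC6, at 2.02 and 0.47 in the 2 libraries, H2BC5 (1.23), H2BC4 (1.15) and H1-2 (1.02), all from multigene families and uncertain.

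Heat shock genes had a median of 0.60 (0.28 in library 1 and 0.91 in library 2, camera adjusted p 0.000403), 11 of 13 higher in both. The call was lost with an estimated correlation, at an adjusted p = 0.714. Members farthest from 0 were HSPA4L at 0.95, HSPA8 at 0.92, HSPE1 at 0.89 and HSP90AB1 at 0.83. Hypoxia and glycolysis genes had a median of 0.42 (0.21 and 0.60, camera adjusted p 0.0132), 11 of 19 higher in both. This call ended with a mean FPKM of at least 5 (adjusted p = 0.0934) and with an estimated correlation (adjusted p = 0.806). The KEGG pathways HIF-1 signaling (median 0.17, camera adjusted p 0.246) and glycolysis (0.102, 0.548) did not pass. Members of the list included hexokinase HK2 at 7.91 FPKM against 14.8 and 20.4, and log2 fold changes of NDRG1 at 0.88, LDHA at 0.81 and PFKFB3 at 0.67. For p53 targets the median of 0.45 (camera adjusted p 0.00204) came from library 1, at 0.72, while library 2 was at -0.03, and 9 of 22 members lay on opposite sides of the control. The call was lost with an estimated correlation, at an adjusted p = 0.806. The 66 genes of the KEGG p53 signaling pathway had a median of -0.079 (camera adjusted p 0.84). CDKN1A, which encodes p21, was at 112 FPKM in the control and at 335 and 174, and PLK3 (1.31), TIGAR (1.14) and ZMAT3 (1.88 and 0.40) were the other leading members. No member of the 3 lists passed adjusted over the list alone or over all genes.

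**Figure D3:**
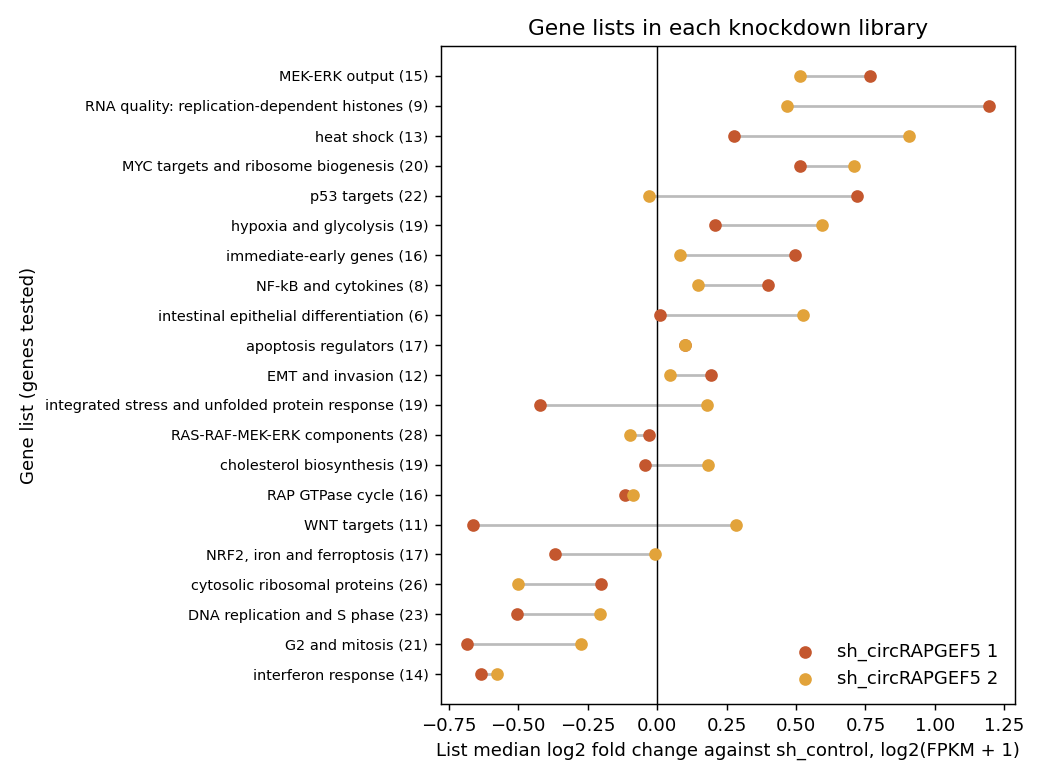
Median log2 fold change against the control, on the log2(FPKM + 1) scale, of the 21 gene lists with at least 5 tested members, 1 point per knockdown library and the number of tested genes in parentheses. MEK-ERK output lies at 0.77 and 0.52, and p53 targets lie at 0.72 and -0.03.

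Lists that did not pass were EMT and invasion (median 0.12, camera adjusted p 0.075), interferon response (-0.56, 0.075), intestinal epithelial differentiation (0.23, 0.13), apoptosis regulators (0.17, 0.214), NF-kB and cytokines (0.33, 0.202), cholesterol biosynthesis (-0.01, 0.462) and WNT targets (-0.25, 0.84). The medians of the cholesterol and WNT lists turned sign with quantile normalization, to 0.049 and 0.003. Knockdown libraries 1 and 2 lay on opposite sides for WNT (-0.66 and 0.28) and cholesterol (-0.04 and 0.18), and were at 0.01 and 0.53 for epithelial differentiation, 0.20 and 0.05 for EMT and 0.40 and 0.15 for NF-kB. The EMT list passed with a mean FPKM of at least 5 (adjusted p 0.00609) and the interferon list with no filter (0.0421). In the EMT list ITGA2 and the urokinase receptor PLAUR (1.55) were higher and fibronectin, FN1 (-1.56), lower, and these 3 passed adjusted over the list alone and not over all genes. In the WNT list AXIN2 (-1.94) and the antagonist DKK1 (1.59) passed adjusted over the list alone in opposite directions. Of 14 tested interferon genes, 9 were lower in both libraries and 2 higher in both, with list medians of -0.63 and -0.58. Among them ISG15 was at 1.16 while OAS3 was at -1.07, and neither of these 2 passed. BMF and TNFRSF10A (1.63) passed adjusted over the apoptosis list alone, and 0 members of the WNT and apoptosis lists passed over all genes. ICAM1 (1.39) led the NF-kB list, CYP51A1 (1.28) the cholesterol list and CA2 (0.34 and 1.41) the epithelial list. Markers of other cell types mostly fell below the filter, with 2 fibroblast, 3 leukocyte and 1 endothelial genes tested and no list test. COL1A1 was at 13.4 FPKM against 4.64 and 8.38, and EGFL7 had a log2 fold change of -0.01. CD68, at 1.30 FPKM against 3.55 and 7.50, passed adjusted over the leukocyte list alone and not over all genes. The other leukocyte genes tested did not go with it: CORO1A (-0.77) was lower in both libraries and HLA-DRA was at -0.59 and 0.62.

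Among 307 KEGG pathways, 16 passed with camera, 11 higher and 5 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.994. Ribosome biogenesis (71 genes, median 0.44, adjusted p 1.1e-07), proteasome (42 genes, 0.44, 4.18e-05) and RNA polymerase (29 genes, 0.54, 0.000125) led the higher pathways. DNA replication (35 genes, -0.40, 0.0379) and the Fanconi anemia pathway (51 genes, -0.34, 0.0254) were among the lower ones.

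The 2 knockdown libraries differed from each other about as much as from the control. Between them 1008 genes differed at least 2-fold, 495 higher in library 1 and 513 higher in library 2, and the SD of the log2 difference over genes was 0.585, against 0.600 and 0.610 for each library against the control. Their fold changes correlated across genes, which are not independent replicates, with Pearson r = 0.533 and Spearman rho = 0.518. Unchanged libraries against the same control gave a simulated mean r of 0.49994 (95% range 0.482 to 0.515), since the control is shared. The covariance was 0.196, against a simulated 0.154 (95% range 0.147 to 0.162). The difference of 0.0411 estimates what the knockdown libraries share beyond the control's own variation, if the control varies as simulated. The simulated spread came from limma's prior and was smaller than the observed SD of 0.585 between the knockdown libraries implies. The difference is therefore likely too large, and the simulated 2-fold counts that follow too low. Simulated unchanged libraries gave 104 genes higher and 104 lower at 2-fold in both, with 95% ranges that end at 124 and 125, against the observed 136 and 191, and independent lists would overlap in 14.7 and 40.4 genes. The simulated libraries share only the control and already exceed the overlap of independent lists. As far as the simulation holds, much of the excess over independent lists thus comes from the shared control.

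Setting each library in turn against the other 2 gave contrasts of similar size. These contrasts cancel when added within a gene. A shift shared by both knockdown libraries therefore recurs in part, with the opposite sign, when either is set apart, and lists can pass again for that reason. With the control apart, 327 genes were 2-fold in both other libraries, with knockdown library 1 apart 260, and with knockdown library 2 apart 314. The limma calls were 2, 36 and 10, with an estimated prior of 10.9, infinite and 45.7 degrees of freedom, and a larger prior by itself eases calls. The lists past the camera threshold numbered 9, 8 and 9. All 9 lists called with the control apart also passed with a knockdown library apart. Heat shock (median -0.63, camera adjusted p 1.32e-05) and hypoxia (-0.51, 0.000124) passed with library 2 apart, and p53 targets with library 1 apart (-0.77, 7.67e-10), each with a smaller p than with the control apart. MEK-ERK output genes passed with library 1 apart, where the other libraries were lower by a median log2 difference of -0.42 (camera adjusted p 4.9e-06), and had a median of -0.20 (0.229) with library 2 apart.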

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

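Limma's voom on the recovered reads, a prior of 5 degrees of freedom and the fits with a knockdown library in the control's place were chosen after seeing the data, and the other alternatives before. Unless a cause is named, the cause was not tested. The 2 limma calls became 0 with no filter on low values, with quantile normalization and with the prior of 5, where CPA4 had an adjusted p of 0.236. They became 1, CPA4, with a pseudocount of 5, without the trend, with robust fitting and with voom. With 0 calls in limma, 1089 genes (no filter), 738 (quantile) and 543 (prior of 5) had an unadjusted p under 0.05. Both calls stayed with a pseudocount of 0.1, a mean FPKM of at least 5 and median-ratio rescaling.

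Genes 2-fold in both libraries numbered 531 with a pseudocount of 0.1 and 101 with 5, which shrinks low genes by construction, and 1449 at 1.5-fold and 14 at 4-fold. Leaving out a knockdown library gave 1023 to 1141, since a single library then decides and no test is left. Genes at 2-fold between the knockdown libraries numbered 1519 and 347 with these pseudocounts, and the correlation of fold changes was 0.511 and 0.552, and 0.550 with quantile normalization.

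With an estimated correlation 0 lists passed instead of 9, and MEK-ERK output (median 0.688, which this alternative cannot move) had an adjusted p of 0.714. That setting leaves camera only 1 residual degree of freedom, so few lists could pass. S phase genes lost their call at an estimated correlation of 0.004, below the preset 0.01. The other called lists had estimates above the preset, from 0.162 (MEK-ERK output) to 0.654 (p53 targets). With 1 residual degree of freedom these estimates are rough, but correlations of that size would make the preset p-values too small. With the preset correlation MEK-ERK output passed under each alternative with a test, with medians from 0.577 to 0.731. Robust fitting has no counterpart in camera and was not run for lists. Immediate-early genes (0.446) and interferon genes (-0.240) passed with no filter, and EMT (0.459) with a mean FPKM of at least 5. S phase and ribosomal protein genes were not called with no filter, at unchanged medians, nor hypoxia genes with a mean FPKM of at least 5, where too few histone genes were left for a test. The components list was at 0.003 with a pseudocount of 5, at 0.038 with median-ratio rescaling, and from -0.097 to -0.029 with a library left out. The p53 list ran from -0.027 to 0.721 that way, so library 1 carries it, and WNT ran from -0.661 to 0.283, integrated stress from -0.421 to 0.181 and cholesterol from -0.042 to 0.184. Medians not called in the planned test changed sign for EMT with no filter (-0.004), WNT with a mean FPKM of at least 5 (0.680), and, with median-ratio rescaling, RAP (0.003) and cholesterol (0.029). With quantile normalization RAP (0.116), WNT (0.003), integrated stress (-0.023) and cholesterol (0.049) did so. RAPGEF5 turned to 0.005, 0.017 and 0.258 with a pseudocount of 5, median-ratio rescaling and quantile normalization. Over all lists, 141 of 166 alternatives with a test kept direction and side of the threshold, and 255 of 268 did for the 34 named genes tested. The count for genes says little, since most were not called in the main test and many were chosen for large fold changes. No paired analysis was possible because the control is a single library.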

Other observations

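The test with a knockdown library in the control's place was chosen after the result was seen. The list of integrated stress and unfolded protein response genes had a median log2 fold change of 0.06 (-0.42 and 0.18 in libraries 1 and 2, -0.023 with quantile normalization), a mean of -0.27 and a camera adjusted p of 0.189 in the direction of the mean, so its median and test differ in sign. It passed with knockdown library 1 (median 0.63, camera adjusted p 0.000173) and knockdown library 2 (-0.29, 0.0139) in the control's place. The 3 members farthest from the control were enzymes of serine and asparagine synthesis. PHGDH was at 32.2 FPKM in the control against 5.03 and 8.95, asparagine synthetase ASNS at 87.7 against 32.4 and 29.1, and PSAT1, which follows PHGDH, at 136 against 51.1 and 90.2. ASNS and PHGDH passed adjusted over the list alone and not over all genes. Of this list, 7 ATF4 targets were set apart after their values were seen: TRIB3, CHAC1, SESN2, DDIT3, DDIT4, ATF5 and CEBPB. They had medians of -0.61 and 0.02 in the 2 libraries, with 2 lower in both. ATF4 itself had log2 fold changes of -0.42 and -0.70 and did not pass. These 7 are not all the targets of ATF4, so their medians do not describe its output as a whole.

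The list of NRF2, iron and ferroptosis genes had a median of -0.35 (-0.37 in library 1 and -0.007 in library 2, camera adjusted p 0.512), and 3 members passed adjusted over the list alone in opposite directions. These were TXNRD1, thioredoxin reductase (42.6 FPKM against 144 and 131), on the higher side, and NQO1 (195 against 72.9 and 78.9) and the cystine transporter SLC7A11 (log2 fold change -1.87) on the lower side.

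Of 15 tested MEK-ERK output genes, 12 were higher in both knockdown libraries, 1 was lower in both and 2 lay on opposite sides, with a median log2 fold change of 0.69. Of these, 6 passed adjusted over the list alone and 0 over all genes. After a trend on gene length and GC content was removed over all tested genes, the median was 0.652 (camera adjusted p 2.29e-07, and adjusted p = 0.756 with an estimated correlation, against 0.714 before the removal). The median that is left argues against such a trend as the whole cause. The histone list, fixed as a possible sign of RNA quality, had medians of 1.19 and 0.47 in the same libraries, with 5 of 9 members higher in both. It may not measure RNA quality and was not tested as a cause. With knockdown library 1 in the place of the control the median was -0.424. This lay between the bounds set for and against a pattern that any library standing apart would give. A shift shared by both knockdown libraries would also give a negative median there, so the value weighs on neither side. An oddity of a single library, the unstated harvest times, and an effect of the knockdown cannot be told apart with 1 control library. No technical explanation of this kind can be excluded, so a link to circRAPGEF5 stays an untested hypothesis.

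The knockdown libraries differed from each other at 2-fold in 1008 genes. Drawing reads at the recovered depth with no difference gave a mean of 1.5 such genes and at most 5 in 200 draws, which argues against counting error of the reads. Removing a trend on length and GC content left 988 of 1006 genes, which argues against that trend. Different hairpins, different harvest times and ordinary culture variation stay open and were not tested, since the labels do not separate them.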
